A study of Caenorhabditis elegans with 2 samples.

How the data were processed

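RNA was measured in mixed-stage embryos of the Caenorhabditis elegans strain BW1943, which carries the gad-1 allele ct226 and the dpy-11 allele e224, a linked marker mutation that shortens the body. Embryos were collected by bleaching from cultures kept at 16 °C or at 25 °C, and 1 stranded mRNA library per temperature was made, per the labels' protocols. Reads were processed with Trimmomatic, TopHat2 and HTSeq, per the submitters' processing notes, which name no versions. The genome build, the annotation and whether the counting used strand are not given in the sources used here.

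The deposited table holds 1 line for each of 19487 genes with annotated introns, with the count of exon reads and the count of intron reads in each library, per the file headers. These counts are not normalized. The columns marked as control and experiment were matched to 16 °C and 25 °C by the same marks in the sample labels. The authors also deposited the summed exon length and summed intron length of each gene. Their fold change is a ratio, the intron-to-exon read ratio at 25 °C over that at 16 °C, and it was recomputed from the counts to within 0.01% in 10860 of the 10860 genes with a finite fold above 0 in the authors' deposited table. The p-value in the authors' deposited table equalled a two-sided Fisher exact test of the 4 counts within 2% in 19487 genes. Its adjusted p equalled that p-value times the number of genes, a Bonferroni adjustment, in 19487 genes of the authors' deposited table.

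The 16 °C library held 21702143 exon and 314675 intron reads, and the 25 °C library 17725845 exon and 449772 intron reads. There were no replicates. For reads, exact binomial intervals at 95% and the floor of 3 counts used against a count of 0 cover counting error only, since reads made by PCR are not independent molecules. Intervals of a share of genes or of a median over genes treat genes as independent. They describe the genes of these 2 libraries and leave out differences between libraries. The main measure was the log2 ratio, 25 °C over 16 °C, of intron to exon reads of a gene, with 0.5 reads added to each count, in the 14972 genes with at least 10 combined reads. Each gene's 4 counts were tested with a two-sided Fisher exact test and adjusted by Benjamini-Hochberg at 0.05. That test compares the reads of these 2 libraries, not the temperatures. Folds of single genes and their intervals are ratios of the counts with nothing added, whereas medians over genes or lists use the 0.5 reads. Gene expression was taken as exon reads scaled by the library total of exon and intron reads, and was described by size alone, at 2-fold, in the 14313 genes with at least 10 exon reads in 1 library.

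The gene lists, the classes of genes, the Fisher test, the comparison with random lists and the rule for named genes were fixed before the data were examined. The rule took gad-1, the 10 largest rises and 10 largest falls of the ratio and the 5 largest of exon reads each way among genes with at least 50 combined reads, and up to 4 members of each list with the largest change. Of the 10 largest rises under that rule, 9 had at most 3 intron reads in either library and 10 had at most 3 exon reads at 25 °C. A second selection, of genes with at least 50 combined intron reads, was therefore chosen after seeing the data, and 4053 genes met it. The 15 lists covered the Prp19 complex (NTC), other spliceosome proteins, transcription elongation, heat-shock, ribosomal protein, histone and collagen genes, markers of endoderm and intestine, body wall muscle, pharynx, epidermis, neurons and the maternal germline, gastrulation and morphogenesis genes, and cell cycle and DNA replication genes. Members were matched by the symbols in the table or by the current symbols of the reference gene names. The match by current symbol was added after seeing the data, and added hrpr-1 to the other spliceosome list. Each list's median was placed among 10000 random lists of the same size matched on expression decile.

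Gene positions and intron numbers came from Ensembl release 115 (WBcel235) by gene identifier, of which 19298 matched and 189 did not. The summed intron length equalled that of this annotation in 65.9% of the table's genes, so positions and intron numbers may differ from those the authors used. Symbols that a spreadsheet had turned into dates (11 genes) were replaced from the reference names. A pair of genes shared 1 sequence name and identical values in 3 cases. Genes with near-identical copies, such as F44E5.4 and F44E5.5 or hsp-16.1 and hsp-16.11, are reported as uncertain, as are genes that overlap another gene.

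The test was checked on counts simulated from the depths of the 25 °C and 16 °C libraries over 14972 genes. It called 45 of 100 genes changed 2-fold, 98 of 100 changed 4-fold and 2 of 14772 unchanged genes. The changed genes were drawn only from those with at least 20 combined intron reads and a low intron share. The simulation held counting error alone, with no other variation between libraries and no shift across genes. Its rates therefore do not carry over to the genes called or not called in the real data. Alternatives were the minimum number of reads, the pseudocount, scaling by the median exon ratio, the fold threshold, unmatched random lists and leaving out each list member. A minimum of 20 combined intron reads, a Bonferroni adjustment at 0.01, lists limited to members with 10 intron reads, counts under 3 set at 3 and library totals without F44E5.4 and F44E5.5 were added after seeing the data. The position of an intron in its gene was not analysed here, because the table gives 1 summed intron count per gene. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.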

Results

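RNA of mixed-stage embryos from 1 gad-1 mutant strain was sequenced at 16 °C and at 25 °C, with 1 library each and no replicates. GAD-1 is a WD-repeat protein needed for gastrulation, and the series title places it in pre-mRNA splicing, transcription elongation and the Prp19 complex (NTC), a set of proteins that joins the spliceosome. The 16 °C library held 22016818 reads in genes and the 25 °C library 18175617. The comparison asks whether introns stay in more transcripts at the higher temperature, and which transcripts differ in level. Both libraries come from the mutant, so temperature and the mutation cannot be separated in any value given here.

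Intron reads made up a larger share of the 25 °C library, and the difference ran across most genes. The share was 1.43% at 16 °C (exact 95% interval 1.42 to 1.43) and 2.47% at 25 °C (2.47 to 2.48), a ratio of 1.73. In the 14972 genes with at least 10 combined reads, the median intron-to-exon ratio was 2.09-fold higher at 25 °C (log2 1.06, quartiles 0.24 and 1.96), and 80.4% of genes lay above 0 (exact 95% interval 79.7 to 81.0). That interval treats genes as independent and leaves out variation between libraries. Of the 14972 genes, 1472 had no intron read in either library, so their value came from unscaled exon reads alone. In 6984 genes with at least 20 combined intron reads, a minimum chosen after seeing the data, the median was 1.96-fold and 86.9% lay above 0. Intron reads of those genes, scaled by library total, had a median log2 of 0.88, and their exon reads one of -0.08. Without that selection, intron reads of the 14972 genes scaled by library total had a median of 0.40, and exon reads of the 14313 genes with at least 10 exon reads in 1 library one of -0.42, so lower exon reads also enter the median ratio.

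**Figure D1:**
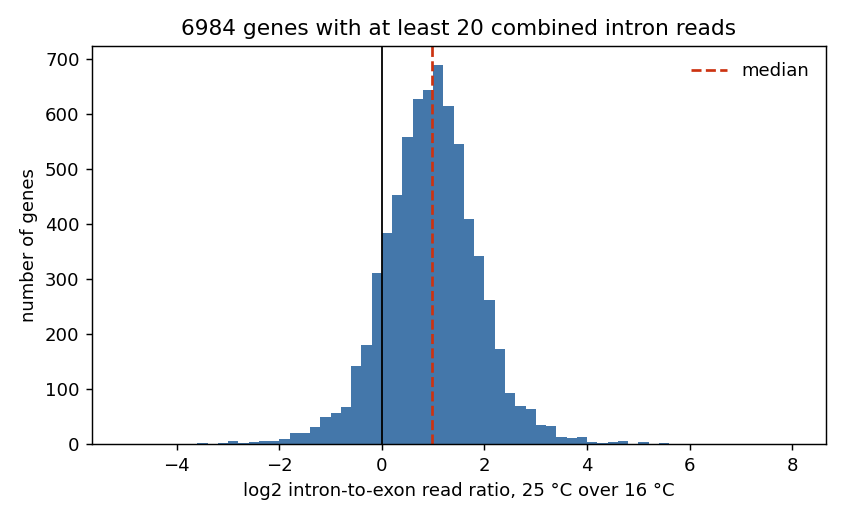
Number of genes (vertical axis) by log2 intron-to-exon read ratio at 25 °C over 16 °C (horizontal axis), for 6984 genes with at least 20 combined intron reads. The solid line marks 0 and the dashed line the median of 0.97.

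The ratio rose in 4200 genes and fell in 92 by Fisher exact test with Benjamini-Hochberg adjustment, and 10680 genes were not called. The rises were 28.1% of the tested genes. By exon level the share called as rises was 2.51%, 14.8%, 35.0% and 59.9% from the lowest to the highest quartile. Counts called in the lists below are to be read against these shares, since they depend on exon level. Of the 4200, 4019 also had more library-scaled intron reads at 25 °C, while 746 had exon reads at least 2-fold lower. The authors' deposited table has 1085 genes past its adjusted p of 0.01, 1082 higher and 3 lower, and all 1085 were also called here. That overlap was fixed in advance, since the same test was used here with a looser adjustment and threshold. The genes lower in the authors' deposited table were aagr-2, mks-5 and T10C6.7, with deposited folds of 0.142, 0.419 and 0.0569. For gad-1 itself (chromosome V, 6431333 to 6433496, minus strand) the exon reads were 3123 at 16 °C and 2748 at 25 °C, a scaled ratio of 1.07 (95% interval 1.01 to 1.12). Its intron reads were 11 and 18, and the ratio of 1.86 (0.83 to 4.36) was not called by the exact test (adjusted p = 0.307). A read count does not show what the ct226 allele does to the protein.

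Among genes with at least 50 combined intron reads, the largest rise was in M03B6.3 (X, 13861277 to 13864292), with 5 intron reads at 16 °C and 56 at 25 °C against 3128 and 150 exon reads, a 234-fold higher ratio (91.9 to 754). This gene overlaps another gene, so its intron reads are uncertain. R193.2 (X, 1132993 to 1148585) had 6 and 90 intron reads and an 86.8-fold higher ratio (36.0 to 249). D2005.6 rose 22-fold (11.2 to 46.9), and B0353.1 19.4-fold (6.99 to 74.6). For klp-7, a kinesin that takes microtubules apart, 1 and 52 intron reads gave a ratio of 34.1 with an interval of 5.83 to 1372, or log2 4.52 with 0.5 reads added to each count. The ratio fell 17.6-fold (5.31 to 90.3) in T10C6.7, 7.06-fold (3.61 to 15.7) in aagr-2, a predicted alpha-glucosidase, and 3.79-fold (2.04 to 6.95) in sod-5, a superoxide dismutase. Library-scaled exon reads, with 0.5 reads added, were higher at 25 °C in T10C6.7 (log2 4.71) and sod-5 (2.53), and lower in aagr-2 (-2.05). For the rises this exon change was -4.10 in M03B6.3, -2.25 in R193.2, -1.83 in D2005.6, -0.45 in B0353.1 and 0.89 in klp-7. Reads are also uncertain for the other named genes that overlap a neighbour, among them klp-7, T10C6.7, aagr-2, isy-1, bcas-2, rps-16, rpl-39, rpl-22, prp-21, ced-10, hsp-70, myo-1 and F49D11.6.

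The NTC list, which includes gad-1, had among the largest rises of the intron-to-exon ratio by list median. The ratio rose in 11 of 13 members, 12 adjusted over the list alone, and none fell. The list median was 3.85-fold (log2 1.95), at percentile 99.9 of matched random lists and 97.4 of unmatched ones, the latter inside the central 95%. isy-1 rose 8.73-fold (3.99 to 21.7), bcas-2 6.44-fold (3.41 to 13), prp-19, the ubiquitin ligase that names the complex, 4.61-fold (2.20 to 10.8) and cdc-5L 4.11-fold (2.90 to 5.97). Exon reads of the list had a median log2 of 0.20 (percentile 70.3 of matched random lists), and 13 of 13 members lay within 2-fold. Among unmatched lists the exon percentile was 97.6, outside the central 95%.

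Ribosomal protein genes combined a higher intron ratio with fewer exon reads. The ratio rose in 50 of 72 members, 53 adjusted over the list alone, with a median of 3.32-fold (percentile 100). rpl-9 rose 13.6-fold (5.61 to 39.9), from 6 to 32 intron reads, and rps-16 8.85-fold (5.39 to 15.1). Exon reads had a median log2 of -1.28 (percentile 0), 2.42-fold lower, with 57 of 72 at least 2-fold lower. rpl-39 was 5.68-fold lower (5.30 to 6.09) and rpl-22 5.59-fold lower (5.29 to 5.91). The list's summed intron reads were 1646 at 16 °C and 1615 at 25 °C before scaling. Library-scaled intron reads of its members had a median log2 of 0.45, against 1.99 in the NTC list. Much of the higher ratio in ribosomal protein genes therefore came with fewer exon reads.

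Other spliceosome genes and transcription elongation genes stood near the typical gene. For the former the ratio rose in 30 of 47, 35 adjusted over the list alone, with a median log2 of 1.06 (percentile 47.6). sftb-1, a U2 snRNP protein, rose 6.23-fold (3.28 to 13) and prp-21 3.76-fold (2.76 to 5.20). For elongation genes it rose in 17 of 27, 22 adjusted over the list alone, with a median of 1.0 (percentile 37.9). ama-1, the large subunit of RNA polymerase II, rose 3.27-fold (2.36 to 4.62), and its exon reads were 2.03-fold higher (1.99 to 2.07). Cell cycle and DNA replication genes rose in 22 of 30, 24 adjusted over the list alone, with a median of 1.14 (percentile 67.5). pcn-1, the replication clamp, rose 4.61-fold (2.90 to 7.62) and mcm-5 3.95-fold (2.68 to 5.97).

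Gastrulation and morphogenesis genes, the process in which gad-1 mutants are known to fail, rose in 15 of 22, 15 adjusted over the list alone, with a median of 0.99 (percentile 33.9). ced-10, a Rac GTPase, rose 5.06-fold (2.85 to 9.46) and mlc-5, a myosin light chain, 4.07-fold (2.60 to 6.47). Histone genes rose in 4 of 12, 4 adjusted over the list alone, with a median of 0.53 (percentile 3.25), and htz-1, the H2A.Z variant, rose 3.29-fold (2.66 to 4.11). Collagen genes rose in 4, 3 adjusted over the list alone, and 108 were not called. Their median of 1.52 (percentile 98.9) rested on genes with few intron reads, and was 0.35 (percentile 0.85) in the 24 members with at least 10.

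**Figure D2:**
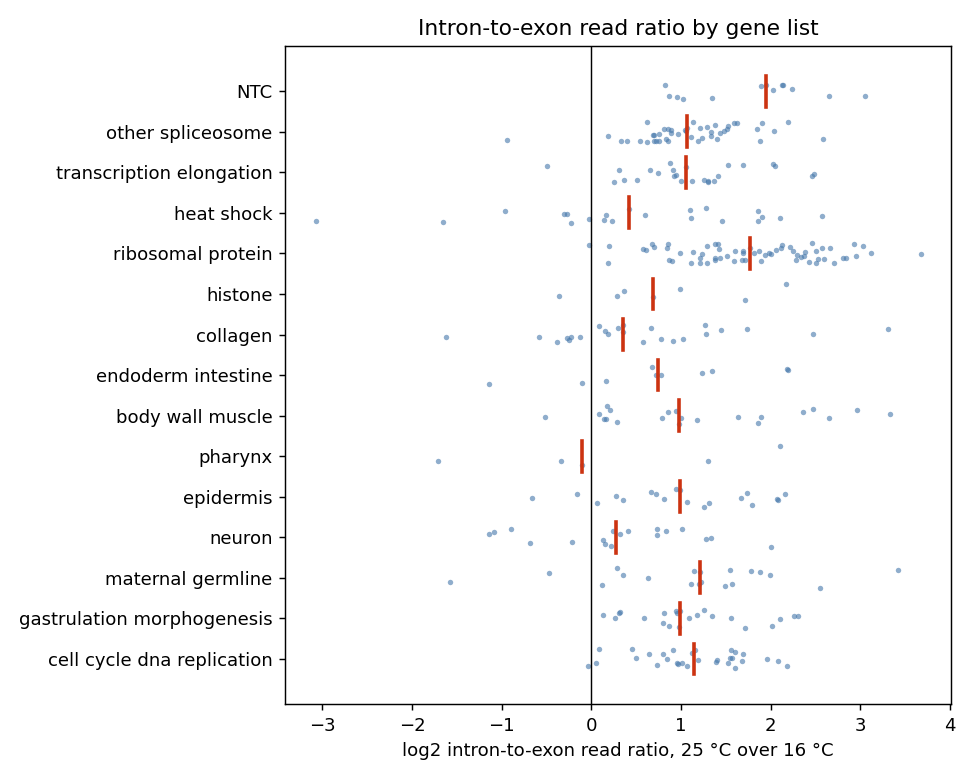
log2 intron-to-exon read ratio at 25 °C over 16 °C (horizontal axis) for members of the 15 lists with at least 10 combined intron reads. Each point is 1 gene and each bar the list median, which is 1.95 for the NTC, 1.77 for ribosomal protein genes and 0.42 for heat-shock genes.

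The change of the intron-to-exon ratio in cell-type markers was uneven by list median, while the counts called also depend on exon level. The ratio rose in 11 of 19 epidermis markers (11 rose and 2 fell adjusted over the list alone; median 0.99, percentile 36.1), with spc-1, alpha-spectrin, 4.29-fold higher (3.07 to 6.10). It rose in 10 of 24 body wall muscle markers, 10 adjusted over the list alone (median 0.96, percentile 28.3), with unc-97 8.01-fold higher (4.76 to 14.3). It rose in 12 of 38 maternal germline genes, 12 adjusted over the list alone (median 1.17, percentile 76.6), where glh-2, a germline helicase, had 1 and 11 intron reads (15.3-fold, 2.22 to 661, or log2 3.42 with 0.5 reads added to each count). The germline median was 1.21 (percentile 78.6) in the 19 members with at least 10 intron reads, and 0.72 (percentile 2.5) over all 38 with counts under 3 set at 3. Neuron markers rose in 7 of 24, 7 adjusted over the list alone, and their median of 0.36 was at percentile 0.3. Intestine markers rose in 4 of 16, 4 adjusted over the list alone (median 1.59, percentile 93.8), and the median was 0.75 (percentile 24.3) in the 10 members with at least 10 intron reads. In the pharynx 2 of 10 rose and 1 fell, and the same numbers held adjusted over the list alone (median 1.73, percentile 97.6). That pharynx median was -0.10 (percentile 0.92) in the 5 members with at least 10 intron reads.

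By list median, exon reads were lowest at 25 °C relative to 16 °C in markers of the pharynx and intestine, followed by collagen and ribosomal protein genes. Intestine markers had a median log2 of -3.08 (percentile 0), 8.44-fold lower at 25 °C, and 16 of 16 lay below 0. ges-1, a gut esterase, was 20.6-fold lower (12.9 to 35.1), and vha-6, a gut proton pump subunit, 8.3-fold lower (7.14 to 9.70). mtl-2, a metallothionein, had 58 reads at 16 °C and 0 at 25 °C, at least 16.0-fold lower against the floor of 3. Pharynx markers had a median of -3.22 (percentile 0), 9.31-fold lower, with 8 of 10 at least 2-fold lower. The pharyngeal myosins myo-2 and myo-1 had 3955 and 2510 exon reads at 16 °C and 121 and 129 at 25 °C, and myo-2 was 27-fold lower (22.5 to 32.6). The pharyngeal troponin tnt-4 was 31.1-fold lower (23.4 to 42.1). With counts under 3 set at 3 the medians were -3.08 and -3.24.

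Body wall muscle markers had a median exon log2 of -0.13 (percentile 8.86), and 5 of 24 were at least 2-fold lower, among them tnt-2 at 3.23-fold (2.72 to 3.86) and mup-2 at 2.74-fold (2.62 to 2.87). Medians were 0.13 for epidermis (percentile 67.6), -0.29 for neurons (percentile 34.9), 0.02 for the maternal germline (percentile 93.6), 0.16 for gastrulation genes (percentile 72.4), -0.04 for other spliceosome genes (percentile 6.70), -0.12 for elongation genes (percentile 14.3) and -0.51 for histones (percentile 2.63). Cell cycle genes had a median of 0.37 (percentile 99.6), with 29 of 30 above 0, and atl-1, the ATR kinase, was 2.51-fold higher (2.37 to 2.65). Collagen genes had a median of -1.84 (percentile 0), or -1.80 with counts under 3 set at 3. Of these, 68 were at least 2-fold lower, 14 at least 2-fold higher and 30 between, and col-77 was 196-fold lower (76.2 to 720).

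Heat-shock genes had a median exon log2 of 0.73 (percentile 100), with 11 of 26 at least 2-fold higher and 5 at least 2-fold lower. F44E5.4, an HSP70-type gene, was 71.4-fold higher (68.8 to 74.2), but its near-identical neighbour F44E5.5 was 65.0-fold higher and the counting may divide their reads in an unknown way. hsp-70 was 48.9-fold higher (36.3 to 67.6). The small heat-shock gene hsp-16.11 was 18.9-fold higher (17.7 to 20.1), with the same uncertainty over its copy hsp-16.1. The mitochondrial chaperone hsp-60 went the other way, 3.49-fold lower (3.26 to 3.73). The intron-to-exon ratio of the list rose in 7 of 26 and fell in 1, also adjusted over the list alone, with a median of 0.32 (percentile 0.01).

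**Figure D3:**
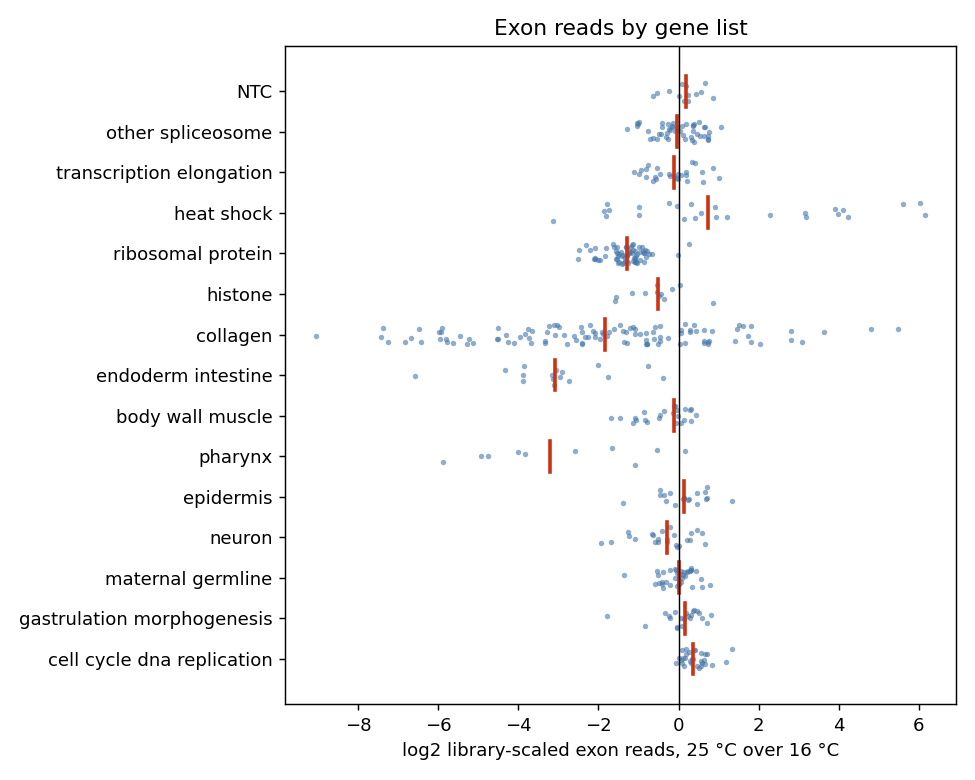
log2 library-scaled exon reads at 25 °C over 16 °C (horizontal axis) for members of the 15 lists with at least 10 combined reads. Each point is 1 gene and each bar the list median, which is -3.22 for pharynx, -3.08 for endoderm and intestine and 0.73 for heat shock; scaling by the median exon ratio would add 0.36 to each value, which turns the small negative medians of neuron, body wall muscle, elongation and other spliceosome lists positive.

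Over all genes, exon reads were at least 2-fold higher at 25 °C in 832 of 14313 genes and at least 2-fold lower in 4811. Of the 14313, 6495 had at least 1000 combined reads. Among those 6495, 159 were at least 2-fold higher and 822 at least 2-fold lower, with a median log2 of -0.08. The largest differences included K01D12.1 (1818 reads and 0, at least 500.3-fold lower), F49D11.6 (952 and 0, at least 262-fold lower) and C49G7.7 (0 and 64, at least 25.8-fold higher). Scaling by the median exon ratio moved every gene up by 0.36 on the log2 scale relative to scaling by library total, and gave 1448 higher and 3926 lower. Under that scaling the medians of the neuron, body wall muscle, elongation and other spliceosome lists became 0.07, 0.24, 0.24 and 0.32.

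By quartile of summed intron length the median log2 ratio went from 1.19 for the shortest to 0.96 for the longest, and from 1.19 in genes with 1 intron to 0.93 in genes with 10 or more. In genes with at least 20 combined intron reads the medians were 0.90 with 1 intron, 1.06 with 2 to 4, 0.99 with 5 to 9 and 0.82 with 10 or more, with no steady order. Chromosome X genes had a median of 1.03 and autosomal genes 1.07, and 0.86 and 0.99 in those with at least 20 combined intron reads. From the lowest to the highest quartile of exon level it was 1.21, 1.11, 0.99 and 1.05, and this order reversed to 0.17, 0.63, 0.96 and 1.06 in the genes of the same quartiles with at least 20 combined intron reads.

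**Figure D4:**
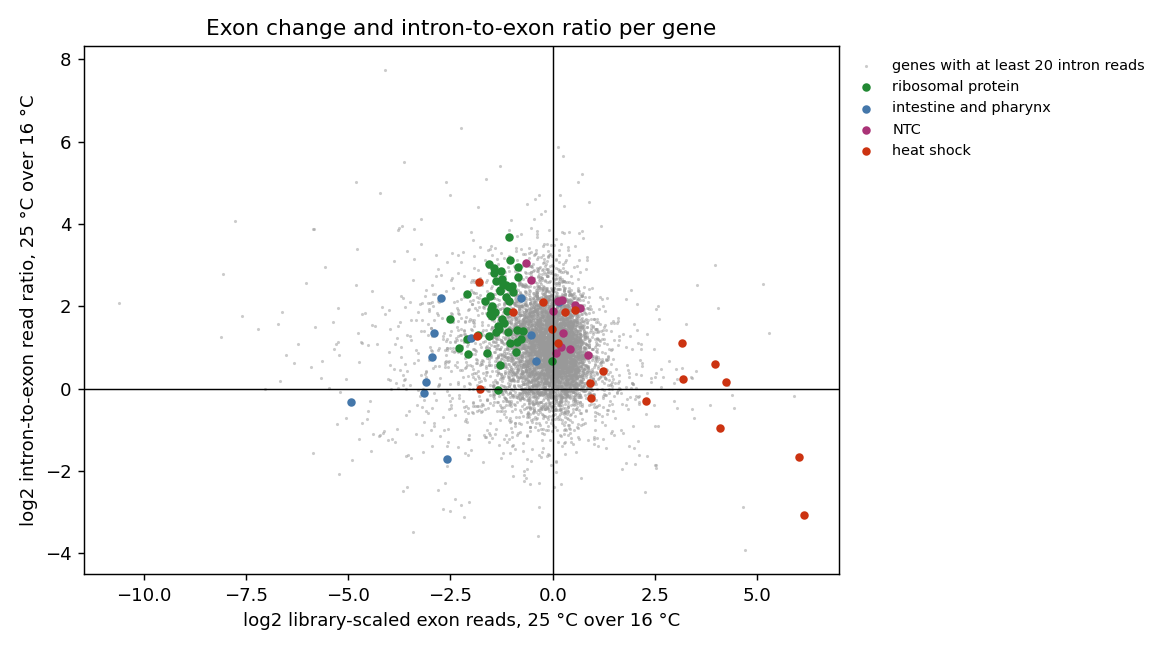
log2 intron-to-exon read ratio (vertical axis) against log2 library-scaled exon reads (horizontal axis), both at 25 °C over 16 °C, for 6984 genes with at least 20 combined intron reads. Coloured points are list members; most of the induced heat-shock genes on the right lie near or below a log2 ratio of 0, and ribosomal protein genes lie at the upper left.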

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

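Settings named as added in the methods were chosen after seeing the data, and the cause was not tested for any difference given here unless the setting itself removes genes. The median ratio of 1.06 was 0.97 with a minimum of 20 combined intron reads, 0.76 for intron reads scaled by the median exon ratio and 0.40 for intron reads scaled by library total. The share of genes above 0 was 76.4% with no minimum, 82.2% at 50 combined reads, 82.1% with a pseudocount of 1, 68.6% for intron reads scaled by library total and 86.9% at 20 intron reads. The Bonferroni adjustment left 1082 rises and 3 falls. It repeats the test, adjustment and threshold of the authors' deposited table, so the equal counts are no separate check. Genes at least 2-fold higher and lower in exon reads (832 and 4811) numbered 1448 and 3926 with the median ratio and 1857 and 6360 with no minimum, and 1605 and 6310 were at least 1.5-fold higher and lower. With unmatched random lists, 11 lists against 6 lay outside the central 95% for exon reads, and 4 against 6 for the ratio. Low exon percentiles of matched lists became higher when unmatched for some lists. They were 97.9 for other spliceosome, 88.8 for elongation, 87.05 for body wall muscle and 39.6 for histone genes. The difference between the highest and lowest quartile of exon level, -0.16, reversed to 0.16 with no minimum, 0.082 in the upper part of expression and 0.39 at 20 intron reads, with quartiles redrawn within the genes kept. The difference by intron number was -0.12 in the upper part and -0.077 at 20 intron reads, and that of chromosome X -0.11 and -0.13. The pharynx median ratio reversed to -0.10 among members with 10 intron reads. Size factors cancel in the intron-to-exon ratio and the pseudocount does not enter the Fisher test, so neither has a value there. No paired analysis was possible because the labels give no replicate numbers and there is 1 library per temperature. Depth limits genes with few intron reads: 1472 tested genes had none.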

Other observations

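All explanations were tested after the main results had been seen, except those on overlapping genes and on splitting the exon reads. The structural muscle genes were picked from the body wall muscle markers when that test was planned, after the exon reads had been seen. Intervals of medians below treat genes as independent and leave out variation between libraries.

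The following genes were chosen after their values were seen and stand for no group. elt-2, the main intestinal GATA factor, had 879 exon reads at 16 °C and 84 at 25 °C, 8.64-fold lower (6.90 to 10.9), and end-1, an earlier endoderm GATA factor, was 4.03-fold lower (2.99 to 5.53). The cuticle genes cut-3 and col-165 were 91.8-fold and 62.1-fold lower.

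The higher intron-to-exon ratio across genes was not what genomic DNA would give: 1322 chemoreceptor genes, mostly silent in embryos, gained library-scaled intron reads per kb at 0.0510 of the rate of other genes. Fewer exon reads alone would leave intron reads level, but in 2304 genes with at least 20 combined intron reads and exon reads within 1.2-fold the library-scaled intron reads had a median log2 of 1.01. Reads of overlapping genes were also argued against, with a median of 0.98 in 3931 genes that overlap no other, under the same minimum, which was chosen after seeing the data. Growth temperature or embryo stage cannot be told apart from loss of GAD-1, because there were 0 libraries of another genotype. A splicing defect from loss of GAD-1 may underlie the pattern, but so may the temperature itself. With 1 library per temperature, a difference between the libraries unrelated to temperature cannot be told apart either.

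The lower exon reads of intestine and pharynx markers could reflect younger embryos at 25 °C or failed differentiation. Structural muscle genes, also late, had a median log2 of -0.80 in 13 genes (95% interval -1.14 to 0.07), short of the -2 set as the bound for younger embryos. That bound was chosen after the exon reads had been seen. Whether these genes would fall as far as intestine and pharynx genes in younger embryos was not examined. The interval also reached past the -1 set as the bound against that explanation, so stage cannot be told apart. A first run held 15 genes, with act-4 and deb-1 added by mistake, and gave -0.47 (95% interval -1.09 to -0.02). The planned 13 were restored after that value was seen, and all 24 body wall muscle markers had a median of -0.13, so the value moves with the genes taken. Transcripts made but left unspliced would keep their intron reads if they were stable. The 19 members at least 4-fold lower in exon reads had library-scaled intron reads at 0.197 of the 16 °C level (388 and 63 reads). Their summed library-scaled exon reads were 9.68-fold lower and their intron reads 5.08-fold lower. Those members were chosen for their exon fall. Intron reads before scaling were 334 and 149 over all tested intestine markers, and 260 and 256 over pharynx markers. Unspliced transcripts that did not last would lose intron reads too, so this explanation stays open.

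Genes at least 4-fold higher in exon reads at 25 °C had little of the rise: 75 such genes with at least 20 intron reads had a median log2 ratio of 0.16. Under the same minimum the median was 0.99 in 5717 genes within 2-fold and 0.93 in 361 genes at least 4-fold lower. It was also 0.17 in 200 genes of the lowest exon-level quartile, so exon level and induction were not separated. The small rise of the induced genes was not limited to heat-shock genes, since the other 67 had a median of 0.17 (95% interval -0.19 to 0.36). Exon reads enter both measures, and with those reads split at random the median was 0.28 (95% interval 0.01 to 0.51). That stays below the 0.7 set for such sharing. The interval reaches the 0.5 also set beforehand, so a part played by shared reads cannot be told apart. A candidate explanation is that newly induced transcripts were spliced like those at 16 °C, which was not tested further.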
